A study of Mus musculus with 2 samples.

How the data were processed

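H3K9me3 chromatin immunoprecipitation followed by sequencing was done on pooled limb tissue of mouse embryos at day 15.5, with 2 biological replicates of 1 group. The samples were grouped and numbered by the biological replicate number in their labels. They came from separate pools of embryos (78 and 62), per the labels. Input libraries were not analysed here.

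Per the deposited descriptions of the lists, each peak list is in narrowPeak format on assembly mm10, each replicate list and a pooled list were called against the same 2 control files, the pooled list used the reads of both replicates, and the replicated list was derived from the pooled list and both replicate lists. The aligner, the peak caller, the threshold and the overlap rule are not given in the sources used here. The deposited score of a peak is a display value that rose with its −log10 p and was not used further. The fold enrichment over control is the authors' own ratio for each peak, by the column order of the format. The −log10 p and −log10 q of each peak are the authors' own values too. Fold and −log10 p served to describe, rank, filter or compare peaks within a list. The smallest −log10 p was 2.02 in replicate 1, 2.01 in replicate 2, 2.08 in the pooled list and 2.19 in the replicated list, so the lists reach down to weak peaks: a −log10 p of at least 5 was met by 19.3% and 17.4% of the replicate 1 and 2 peaks and by 77.2% of the replicated peaks. A q of 0.05 or less was met by 10.9%, 17.4% and 86.3%. The files give no read totals, so the depth is unknown and no interval that needs it is given.

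Genes came from the GENCODE annotation, release M21, and sequence from the GRCm38 reference, the same build as mm10. Tests used 21 chromosomes, except that of the centromeric ends, which left out Y and used 20. Peaks on other contigs were counted but not tested. Runs of at least 100 unknown bases were removed as gaps. In the circular-shift permutation test, all peaks of a chromosome were moved together by 1 random offset around its gap-free sequence, which keeps peak widths, peak clusters, gene lengths and gene clusters. The test was two-sided, with 100000 shifts for the overlap of the replicates, the gene lists and the zinc finger positions, 10000 for genomic positions and most alternatives, 2000 for reciprocal overlap and 1000 for genomic positions in single replicates. A replicate 1 peak counted as shared when at least 50% of its length was covered by replicate 2 peaks. A gene counted as marked when at least 1 bp of its body, from annotated start to end, lay under a replicated peak. Each list of genes was tested by its count of marked members, with Benjamini-Hochberg adjustment over 11 lists and a threshold of 0.05. The start and the last exon of zinc finger genes were compared by an exact McNemar test. Bases were assigned to promoters (within 1 kb of a start) first, then to exons, introns and intergenic sequence.

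The 11 lists, fixed before the data were examined, were zinc finger genes, clustered protocadherin genes, olfactory receptor genes, vomeronasal receptor genes, X-linked germline cluster genes, imprinted genes, germline genes, limb patterning and skeletal genes, genes of other cell types in the limb, genes of lineages outside the limb, and housekeeping genes. The first 5 were taken by gene symbol pattern and the others by name. The rule for named genes, set at the same time, took up to 4 members of each list with the most gene-body bases under replicated peaks, the 10 protein-coding genes with the most such bases, the genes that overlap or lie nearest to the 10 replicated peaks of highest fold, up to 3 protein-coding genes in each of the 10 domains with the most peak bases, and Hoxa13, Hoxd13, Shh, Sox9, Col2a1, Actb and Gapdh. Coordinates are 1-based.

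Alternatives changed 1 choice at a time: the overlap that counts as shared, a −log10 p of at least 5, the pooled list or a single replicate list, the window (2 kb either side of the start, or the body with 10 kb either side), at least 500 bp of peak in the body, random lists of genes matched on length in 20 classes (10000 draws), shifts with gaps included, a promoter or start window of 2 kb, and merge distances of 5 and 50 kb. A single replicate list stands for leaving the other replicate out. Peaks of unique sequence, a set added after the data were seen, had at least 90% of their 31-base words present once in the 21 chromosomes, and numbered 3756 of 5363.

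The shift test was tested on simulated data before use. With 1000 shifted copies of the replicated peaks in place of the real ones, 1.0% to 4.9% of tests gave a p under 0.05 in the 11 gene lists, which held 2236 entries. Those copies came from the same kind of shift as the test. A rate near or below the threshold was therefore built in and checks only the calculation, not whether shifts imitate the genome. With a 600 bp peak added to 20% or 10% of 200 random genes, 3 of 3 sets gave a p under 0.05 each time, and with 5% 1 of 3 did. Those genes were scattered, unlike the clustered families among the lists, for which recovery was not tested. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9 were used.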

Results

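Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of silent chromatin, was mapped by chromatin immunoprecipitation and sequencing in mouse limb tissue at embryonic day 15.5. The 2 biological replicates came from mixed-sex pools of strain B6NCrl. Replicate 1 held the limbs of 78 embryos and combined 2 technical replicates, while replicate 2 held the limbs of 62 embryos and had 1 technical replicate. The tissue made up the only group, so the questions that the design answers were where the mark lay and how far the replicates shared it. No second condition entered any comparison. The replicate 1 list held 27613 peaks with a median width of 215 bp that covered 6957 kb, or 0.257% of the gap-free sequence of the 21 chromosomes. The replicate 2 list held 37058 peaks with a median width of 222 bp that covered 9759 kb, or 0.362%. A list called on the pooled reads of both replicates held 26476 peaks, of which 5583, with a median width of 376 bp and a covered length of 2666 kb, made up the list named replicated. The authors' fold enrichment over control had a median of 2.98 in replicate 1, 3.02 in replicate 2 and 3.23 in the replicated list. Read totals were not among the values analysed here, so the depth of each replicate is unknown.

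The replicates shared far more H3K9me3 peaks than shifted positions gave, yet most peaks of either list were not shared. Of the 27301 replicate 1 peaks on the 21 chromosomes, 3585 (13.1%) had at least 50% of their length under replicate 2 peaks, against 112.6 ± 15.3 (SD over shifts) after circular shifts. The excess was 31.8-fold (two-sided permutation p = 2e-05, the smallest that 100000 shifts can give). Seen from replicate 2, a count added after the data were seen, 3164 of 36733 peaks (8.61%) were covered by replicate 1. Sharing was highest among the strongest peaks: with contigs included, it was 11.3%, 9.82%, 12.3% and 21.8% from the lowest to the highest quartile of fold enrichment in replicate 1, and 6.49%, 6.42%, 7.34% and 16.0% in replicate 2. Among peaks with a −log10 p of at least 5, 29.5% of 5327 in replicate 1 and 22.9% of 6445 in replicate 2 were shared. When both lists were first limited to such peaks, 855 of 5126 replicate 1 peaks (16.7%) were shared against 5.14 expected, so the ratio of 166 rests mostly on the lower expected count. Both lists were called against the same 2 control files, which the shifts do not imitate, so part of the excess may come from the shared controls.

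The replicated list, on which the gene comparisons rest, was itself checked against the other lists. All of its 5583 peaks had the position and fold of a pooled peak. Of these, 4747 (85.0%) touched both replicate lists, 823 (14.7%) touched exactly 1 of them and 13 (0.233%) touched neither. Requiring that both replicates cover at least 50% of a pooled peak gave 3639 peaks, and all 3639 were in the replicated list. With 50% of either peak as the rule, tried after the data were seen, the number was 4712, again with all of them in the list, which held 871 more. With at least 1 bp in both replicates, 5061 pooled peaks qualified, of which 4747 were in the list and 314 were not, while 836 listed peaks did not qualify. None of the rules tried gave the replicated list exactly. With a −log10 p of at least 5 required in every list, 809 peaks remained.

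Zinc finger genes, imprinted genes and clustered protocadherin genes carried H3K9me3 far more often than shifted peaks did. A replicated peak lay in the body of 110 of 419 zinc finger genes (26.3%), 29 of 48 imprinted genes (60.4%) and 38 of 57 clustered protocadherin genes (66.7%). Shifted peaks touched 20.5 ± 6.59, 4.03 ± 2.08 and 5.18 ± 8.28 genes (mean ± SD), so the observed counts were 5.37, 7.19 and 7.33 times the expected ones. Adjusted permutation p was 0.00011 for zinc finger and imprinted genes and 0.017 for protocadherins (two-sided, Benjamini-Hochberg over 11 lists). Across all protein-coding genes, 1207 of 21938 (5.50%) had a replicated peak. The ratios were smaller in each replicate list alone, at 2.09 and 1.83 for zinc finger genes, 2.50 and 1.87 for imprinted genes, and 2.08 and 1.86 for protocadherins in replicates 1 and 2, with adjusted permutation p of 0.0044 or less in each.

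**Figure D1:**
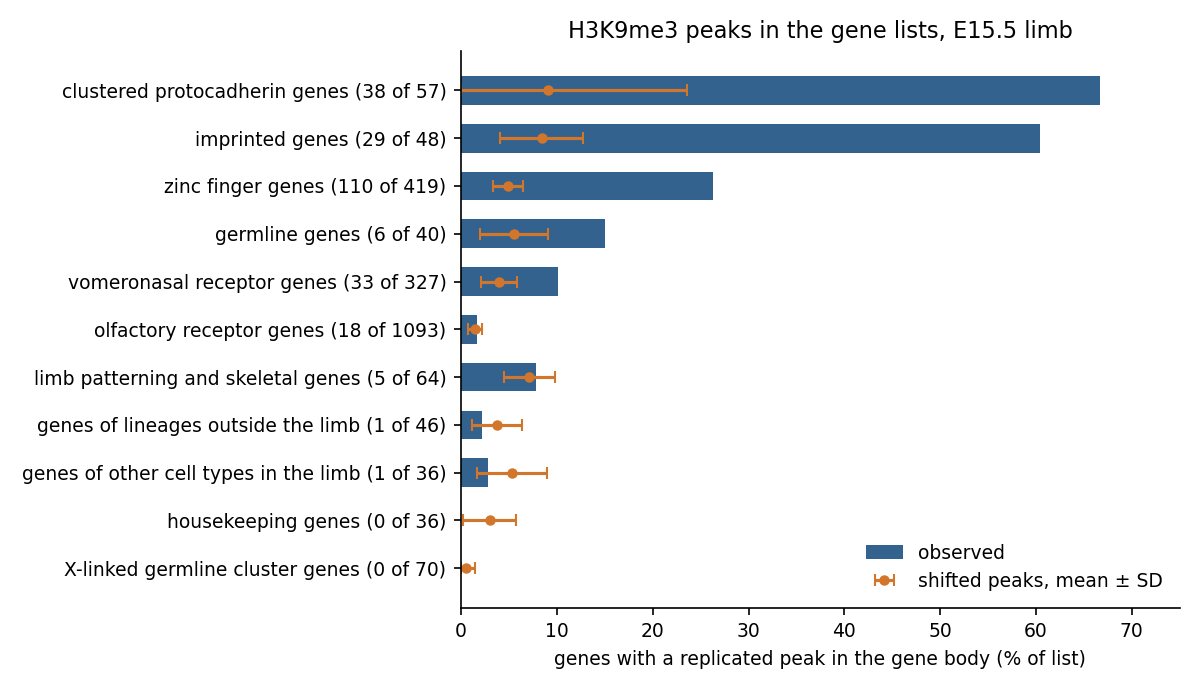
Share of the genes of each list with a replicated H3K9me3 peak in the gene body (x axis, percent of the list; bars) and the mean ± SD over 100000 circular shifts of the peaks (points with error bars, stopped at 0). Observed over expected decreases from top to bottom, from 7.33 for the protocadherins to 0 for the housekeeping and X-linked germline lists.

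Zinc finger genes encode DNA-binding proteins, many of which recruit the machinery that places H3K9me3. Peaks lay on their last exon, where the zinc finger repeats are commonly encoded, and rarely at their start. Of 415 zinc finger genes with at least 2 exons, 92 (22.2%) had a replicated peak on the last exon, 26.6 times the 3.46 expected (two-sided permutation p = 2e-05, the smallest possible), while 6 (1.45%) had one within 1 kb of the start, against 2.92 expected (permutation p = 0.23). The last exon alone was marked in 86 genes, both places in 6 and the start alone in 0 (exact McNemar p = 2.6e-26). The windows were of similar size, with a median last exon of 2243 bp and a start window of 2001 bp. In the replicate 1 list the last exon alone was marked in 107 genes and the start alone in 2, and in the replicate 2 list in 110 and 1. The last-exon ratio was lower in these lists, at 8.03 and 6.60. The start ratio was 0.775 and 0.850 there, against 2.06 in the replicated list. Neighbouring genes of a cluster are not independent, which the McNemar test leaves out.

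The zinc finger genes with the most bases under replicated peaks were Zfp110 (chromosome 7, 12834761 to 12850577), with 9325 bases in 13 peaks, or 59.0% of the gene body, Zfp873 on chromosome 10 (8820 bases, 10 peaks), Zfp936 on chromosome 7 (8692 bases, 20 peaks) and Zfp981 on chromosome 4 (8619 bases, 18 peaks). Zfp110 had 5760 bases under peaks in replicate 1 and 10117 in replicate 2, and Zfp873 had 7966 and 8338. Marked zinc finger genes were spread over 17 chromosomes, with 28 of 102 on chromosome 7, 14 of 41 on chromosome 13, 12 of 46 on chromosome 17 and 9 of 20 on chromosome 9. On chromosomes 1, 3 and 14, 0 of 13 carried a replicated peak. A peak of each replicate list lay in 147 of the 419 genes.

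**Figure D2:**
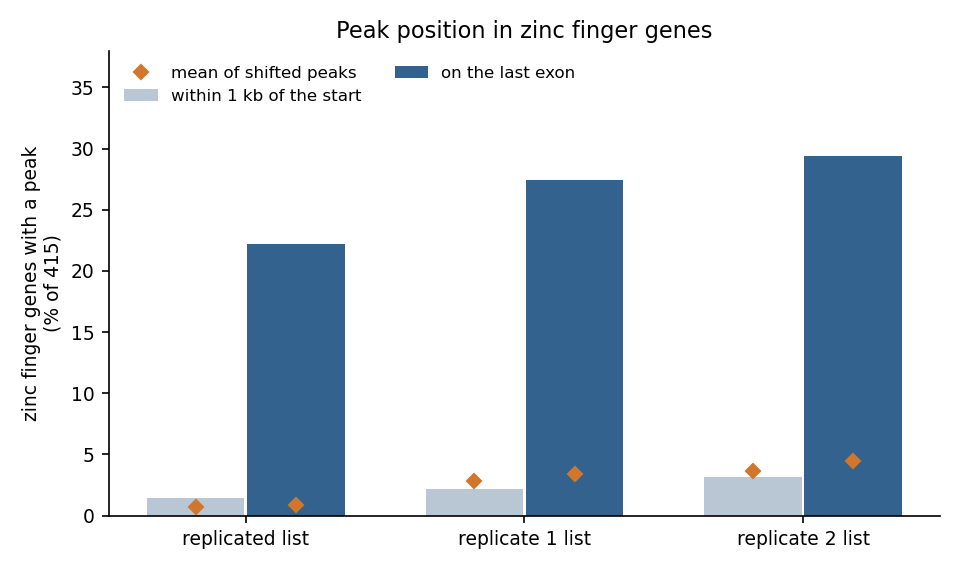
Percent of 415 zinc finger genes with a peak within 1 kb of the start (pale bars) or on the last exon (dark bars), for the replicated list and each replicate's own list; diamonds give the mean of shifted peaks. The last exon was marked in 22.2%, 27.5% and 29.4% of the genes, and the start in 1.45%, 2.17% and 3.13%.

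The clustered protocadherins, cell surface proteins that neurons use to recognise one another, carried the domain with the most H3K9me3 peak bases. A replicated peak lay within 2 kb of the start of 18 of 21 gamma, 12 of 22 beta and 4 of 14 alpha genes, or 34 of 57 in all, against 0.501 expected (67.8-fold, adjusted permutation p = 0.0022). The stretch over the gamma cluster (chromosome 18, 37657756 to 37774884) held 65 replicated peaks and 53379 peak bases in 117 kb, with a median fold of 3.97, and replicates 1 and 2 had 90 and 107 peaks there. Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhgb1 had 53038, 52098, 50884 and 49675 bases in their bodies, and Pcdhga4, Pcdhgb2 and Pcdhga5 had 48124, 45985 and 43089. Those bodies overlap, because the gamma genes share their 3′ exons, and the annotated readthrough genes Gm42416, Gm37013 and Gm37388 run from within the alpha cluster into the gamma cluster with 75955, 75234 and 74933 bases. The 38 marked genes therefore formed 13 groups of overlapping bodies, all within a single region of chromosome 18. Because the genes lie together, a shift tends to touch many of them or none. The highest shifted counts were 43 marked bodies and 36 marked starts, above the 38 and 34 observed. The 7.33-fold and 67.8-fold ratios thus rest on a single region.

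**Figure D3:**
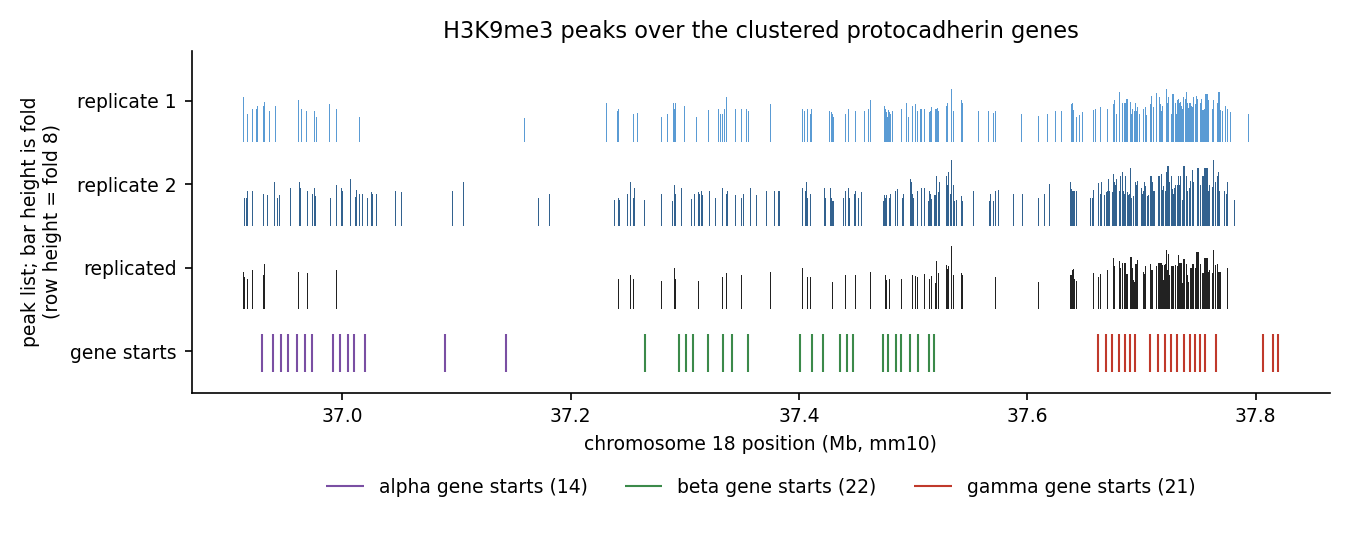
Peaks over the clustered protocadherin genes on chromosome 18 (x axis, position in Mb, mm10), with 210 peaks of replicate 1, 274 of replicate 2 and 127 of the replicated list drawn as bars whose height is the authors' fold (1 row height is a fold of 8; bars are at least 800 bp wide), and ticks at the starts of 14 alpha, 22 beta and 21 gamma genes. The replicated peaks are densest over the gamma genes, between 37657756 and 37774884.

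Imprinted genes, expressed from 1 parental allele, carried discrete peaks in both replicates. The 29 marked genes formed 22 groups, with genes of overlapping bodies counted as 1 group. Genes of different groups can still be neighbours, so the 22 are not shown to be separate regions. A replicated peak lay within 2 kb of the start in 17 of the 48, against 0.574 expected (29.6-fold, adjusted permutation p = 0.0022). Gnas, which encodes a G protein subunit (chromosome 2, 174284320 to 174346744), had 6832 bases in 6 peaks with a highest fold of 5.34. Airn, a long noncoding RNA antisense to Igf2r, had 4454 bases in 9 peaks, Grb10, a growth-restraining adaptor, 2403 bases in 4, and the potassium channel gene Kcnq1 2376 bases in 4. The same 2376 bases lay in Kcnq1ot1, the antisense RNA inside Kcnq1. Gnas had 5274 bases under peaks in replicate 1 and 7098 in replicate 2, and Airn had 3620 and 6551. Of the 48 genes, 33 had a peak in each replicate list.

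Among the germline genes, which act in germ cells and meiosis, a replicated peak lay in the body of 6 of 40, namely Dazl, Ddx4, Meioc, Taf7l, Tdrd1 and Tdrd9, which was 2.70 times the 2.22 expected and did not pass the test (adjusted permutation p = 0.087). Within 2 kb of the start, 4 of 40 had a peak (Dazl, Ddx4, Meioc and Taf7l) against 0.303 expected (13.2-fold, adjusted permutation p = 0.0029). Dazl and Tdrd9 were named after their values were seen. Meioc had 973 bases under a replicated peak with 0 bases in replicate 1 and 1372 in replicate 2, while Ddx4, a germ cell RNA helicase, had 563 with 428 and 264. In the replicate 1 list alone, the body ratio was 0.803. X-linked germline cluster genes carried 0 replicated peaks among 70 genes, against 0.348 expected (adjusted permutation p = 1). With so few expected, a count of 0 could not pass, so the test does not show whether they were marked less often.

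Vomeronasal receptor genes, which detect pheromones, carried replicated peaks in 33 of 327 bodies, 2.57 times the 12.9 expected (adjusted permutation p = 0.037). The marked members were 21 of 120 Vmn2r genes and 12 of 207 Vmn1r genes. Vmn2r60 (1711 bases), Vmn2r53 (1251), Vmn2r103 (1131) and Vmn2r61 (1099) had the most peak bases. The call was lost with stricter peaks (adjusted permutation p = 0.081), with at least 500 bp of peak (0.15), with the window at the start (0.68) and, in settings added after the data were seen, with peaks of unique sequence (0.2) and peaks touching both replicate lists (0.06). The ratios in these settings were 2.50, 2.58, 2.01, 2.02 and 2.59, in that order. Olfactory receptor genes were marked about as often as shifted positions, in 18 of 1093 bodies against 15.8 expected (1.14-fold, adjusted permutation p = 1). Olfr348, Olfr1346, Olfr846 and Olfr398 led them, with 740, 705, 673 and 609 bases.

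Genes of limb patterning and skeleton, of other limb cell types, of lineages outside the limb and of housekeeping gave counts that did not pass the test. Replicated peaks lay in 5 of 64 limb genes, 1.10 times the 4.55 expected, in 1 of 36 genes of other limb cell types (1.92 expected), in 1 of 46 genes of outside lineages (1.75 expected) and in 0 of 36 housekeeping genes (1.07 expected), each with an adjusted permutation p of 1. With so few genes expected, a count of 0 could not pass the test for housekeeping genes (unadjusted permutation p = 0.66), so these tests do not show whether such lists were marked less often. The limb genes were Fgfr2 (1471 bases), Sox5 (820), Prrx1 (368), Bmp7 (338) and, named after its value was seen, Runx2 (180), and 0 of 64 had a peak within 2 kb of the start. The annotated body of Fgfr2 spans 2961 kb, so its peaks need not lie near the receptor's exons. Ttn, the giant muscle protein gene, had 3304 bases in 6 peaks, and Cyp3a11, a liver enzyme gene, 296 bases in 1. In the replicate 2 list alone, genes of outside lineages reached 1.73 times the expected count (adjusted permutation p = 0.031), against 1.12 in replicate 1 alone (0.9). Hoxa13, Hoxd13 and Shh, which pattern the digits, the cartilage regulator Sox9, and Actb and Gapdh had 0 peak bases in every list. The cartilage collagen gene Col2a1 had 0 replicated bases, 452 in replicate 1 and 254 in replicate 2.

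Over the genome, replicated H3K9me3 peaks favoured exons and promoters over introns. Exons outside promoters held 11.7% of peak bases against 3.51% ± 0.389 (SD over shifts) after shifting (3.35-fold), and promoters within 1 kb of a start held 11.6% against 6.67% ± 0.642 (1.74-fold). Introns held 31.1% against 39.9% ± 2.34 (0.780-fold), and soft-masked repeats made up 28.2% against 34.0% ± 1.02 (0.829-fold). The G+C content was 46.9% against 42.1%. Adjusted permutation p was 0.00024 for each of these 5 measures (two-sided, 10000 shifts, Benjamini-Hochberg over 6 measures). Intergenic sequence held 45.5% against 49.9% ± 2.55 and did not pass the test (adjusted permutation p = 0.086). In the lists of replicates 1 and 2 alone, the exon ratio was 1.68 and 1.65 and the promoter ratio 1.20 and 1.17. The intergenic ratio turned to 1.05 and 1.06 there (adjusted permutation p = 0.026 and 0.006). Shifts also land on repeated sequence. In a shifted copy of the list, 13.2% of peaks had a median of at least 2 copies of their 31-base words, against 2.29% of the replicated peaks. Repeats where reads cannot be placed uniquely could therefore lower the soft-masked share, so it does not show that the mark avoids repeats. Exon and promoter shares were set against the same shifted positions, and promoters were not tested at a matched repeat share.

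The replicated peaks of highest fold lay in the genes Asmt, Klf14, Plec, Zfp763 and Zfp810 or between genes. Between genes, the nearest protein-coding genes were vomeronasal receptor or zinc finger genes, up to 30.0 kb away. No expected count of such neighbours was computed, and pseudogenes were not among the genes used. The highest peak, at a fold of 6.81 (chromosome 18, 3117850 to 3119603), lay between genes, 2.89 kb from Vmn1r238, and the next, at 6.58, lay 6.60 kb from the same gene. Asmt, whose enzyme makes melatonin, held peaks at 6.47 and 6.37 (X chromosome, 170674577 to 170675318 and 170675497 to 170677365) and had 69.0% of its 5.41 kb body under replicated peaks. The transcription factor gene Klf14 held a peak at 6.46 (chromosome 6, 30957031 to 30958774) and Plec, which encodes the cytoskeletal linker plectin, held one at 6.37 (chromosome 15, 76173309 to 76177177), both entirely exonic. Zfp763 and Zfp810 each held an entirely exonic peak at 6.20. The remaining peaks lay 30.0 kb from Zfp987 (6.31) and 24.0 kb from Vmn1r77 (6.22). The 4 peaks outside genes had 57.4% to 68.1% of their 31-base words present once in the 21 chromosomes, below the 90% set for unique sequence, while the 6 within genes had 94.1% to 100%. At Klf14 the fold was 5.15 in replicate 1 and 7.12 in replicate 2, and at Asmt 5.69 and 5.28 for the stronger peak.

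Chromosomes 7 and 17 carried the densest H3K9me3 peaks in each of the 4 lists, and the X and Y chromosomes the sparsest. Chromosome 7 held 858 replicated peaks, or 16.0% of those on chromosomes, at 6.05 per Mb, which was 2.99 times the mean of the 21 chromosomes. The ratio was 2.35 on chromosome 17 (436 peaks) and 1.63 on chromosome 4 (503 peaks), with 0.229 on X (76 peaks) and 0.0448 on Y (8 peaks). Replicates 1 and 2 gave 2.11 and 2.06 on chromosome 7, 1.67 and 1.66 on chromosome 17, 1.21 and 1.20 on chromosome 4, and 0.345 and 0.342 on X. Chromosome 5 stood at 1.18 and 1.23 in the replicates, so chromosomes 4 and 5 changed order between them, and at 1.24 in the replicated list. These densities were not tested. The pools were of mixed sex, so X and Y were present in fewer copies on average than the other chromosomes. How far this, or sequence where reads cannot be placed uniquely, lowered their peak counts is unknown. The low values on X and Y thus do not show that the mark is sparse there.

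**Figure D4:**
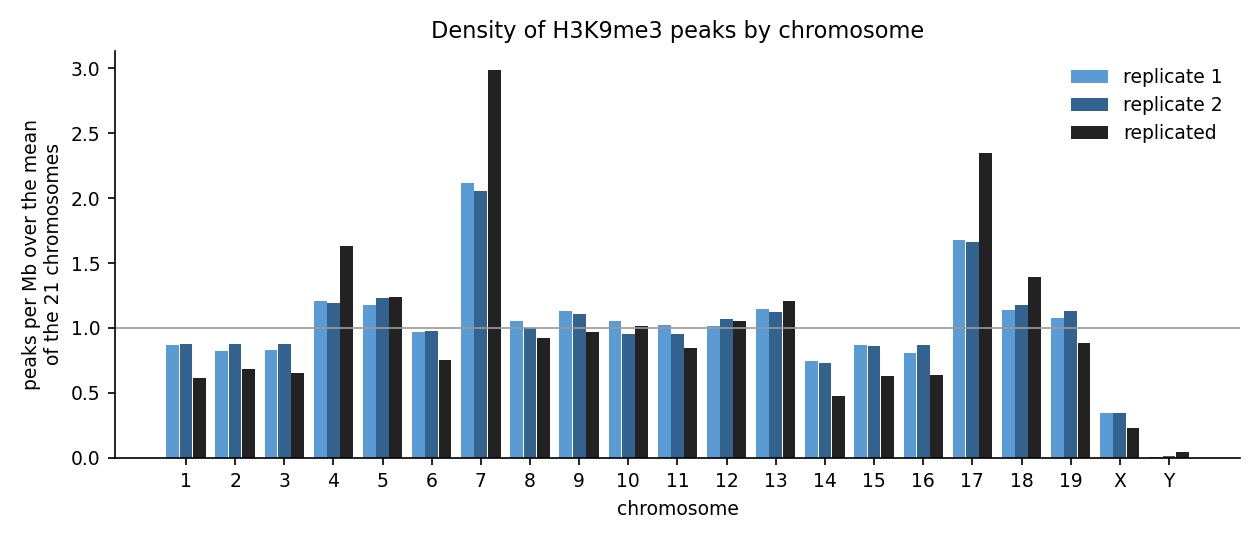
Peaks per Mb of gap-free sequence on each chromosome (x axis) divided by the mean of the 21 chromosomes (y axis; the line marks 1), for replicate 1, replicate 2 and the replicated list. Chromosome 7 is highest in the 3 lists, at 2.11, 2.06 and 2.99, and X and Y are lowest.

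Merging replicated peaks within 10 kb gave 3432 domains, of which 2735 held a single peak and 148 held at least 5. Those 148 domains held 1504 peaks (26.9% of the list). After the gamma protocadherins, the domain on chromosomes with the most peak bases lay across Mroh2a and the end of the Ugt1a genes, which encode glucuronidation enzymes (chromosome 1, 88211445 to 88258303, 27 peaks, 38804 bases). Mroh2a had 76.5% of its body under replicated peaks, and the overlapping Ugt1a7c and Ugt1a10 had 6978 and 6080 bases. A neighbouring domain in Trpm8, the cold-sensing channel gene (88283343 to 88310443), held 16 peaks and 15768 bases. The median fold was low in both, at 2.57 and 2.28. Domains on chromosome 4 (121978215 to 122059888, 37 peaks; 3050006 to 3090823, 15 peaks) and chromosome 3 (3001006 to 3033527, 24 peaks) held no protein-coding gene, and 4 of the 10 largest domains lay on unplaced contigs. The number of domains with at least 5 peaks was 465 in replicate 1 and 654 in replicate 2 alone.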

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

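The tests of shared reads, of control reads and of reference copies in this part were chosen after the results were seen; the tests of exons at matched G+C content and repeat share were set before their values were known.

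H3K9me3 also lay on sequence that no gene comparison used: 220 replicated peaks (3.94% of the list) were on 20 contigs outside the 21 chromosomes, 62 of them on 1 unplaced contig. No expected count was computed for contigs.

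Reads shared between near-identical copies may have raised the counts of zinc finger, protocadherin and imprinted genes. With peaks of unique sequence, 98 zinc finger, 34 protocadherin and 29 imprinted genes were still marked. These were 6.12, 7.89 and 8.74 times the shifted counts (adjusted permutation p = 0.0011, 0.039 and 0.0011). The lowest ratio of 6.12 argues against reads shared between copies identical over 31 bases on the chromosomes as the whole cause. The filter counted only exact words on the chromosomes. Copies that differ in sequence, or that lie on contigs, could pass it, so reads shared with those copies stay open. For the vomeronasal receptors the ratio went from 2.57 (33 genes against 12.9 ± 6.09, SD) to 2.02 (20 against 9.91 ± 4.82) and the call ended (adjusted permutation p = 0.2). Shared reads stay open there, because the remaining peaks are fewer and the ratio still lies above 1. The design has no second group, so no biological explanation was tested.

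The long domains at Mroh2a, Ugt1a and Trpm8 on chromosome 1 had a median fold of only 2.34 over 43 peaks. At the same fold (within 0.1), their −log10 p lay above that of other replicated peaks by a median of 6.03, and in 38 of 43 peaks, which is consistent with more reads there in the control as well, as extra copies of the region in these animals could give; control reads were not analysed here. Their peaks were also wider (median 1127 bp against 375 bp), and with width matched within 1.5 times the median difference was 2.84 over the 32 peaks with at least 5 matches, 27 of them above 0, while 11 peaks had too few matches, so width stays open for those. Several identical copies on the reference chromosomes are argued against, since 97.7% of these peaks were of unique sequence. Copies that differ in sequence, or that lie on contigs, stay open, because only exact words on the chromosomes were counted. No biological explanation was tested.

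Outside the listed zinc finger and protocadherin genes and the protocadherin readthrough genes, 11.1% of replicated peak bases were exonic (promoter exons included), against 4.77% of random 500 bp windows. The exclusion followed the symbol lists, so zinc finger genes of other names and pseudogenes stayed in. Exons of every annotated gene class counted. The higher exon share is therefore not shown to lie outside all zinc finger sequence. A bias towards G+C-rich sequence might account for the higher exon share. Yet windows of the same G+C content were 7.66% exonic, a difference of 3.47 ± 0.513 percentage points (bootstrap SE over 4858 peaks). Windows of the same soft-masked share, a stand-in for repeats lost to unique mapping, differed by 5.76 ± 0.540 points. The bootstrap drew peaks as if they were independent, although peaks cluster, so both SEs may be too small. With that limit, the differences argue against G+C content alone and repeat share alone as the whole cause. Windows were not matched on both at once, so their joint effect stays open. A G+C bias as part of the cause stays open too, and no biological explanation was tested.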

How the results depend on the processing

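Peaks of unique sequence, peaks touching both replicate lists, the 50%-of-either rule and the count from replicate 2 were added after the data were seen; the other alternatives were planned, and all planned ones were run. Of the values recomputed under an alternative, 17 turned direction, 6 lost a call and 4 gained one in the same direction, and 14 without a test moved. Of the 17, 3 passed the threshold where the reported value did not: outside lineages without replicate 1 (adjusted permutation p = 0.031) and intergenic sequence without replicate 1 (0.006) and without replicate 2 (0.026). The remaining 135 kept their direction and side of the threshold or, without a test, stayed within 1.5 times (counts) or 1 SD between the replicates (densities). The zinc finger call held except with the 2 kb window at the start, and the protocadherin and imprinted calls held in every alternative run, at 1.86 to 67.8 and 1.87 to 29.6 times the shifted counts. The replicate overlap ran from 22.7-fold to 166-fold, and the last exon was marked 9.20 to 40.0 times as often as the start in zinc finger genes. The overlap and the rebuilt list need both replicates and have no value without one.

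With a −log10 p of at least 5, the rebuilt list fell from 3639 to 809 peaks, vomeronasal receptors had a ratio of 2.50 with no call, olfactory receptors 0.972, and intergenic sequence 0.871 with a call (adjusted permutation p = 0.025). Densities were 2.42 on chromosome 17, 1.70 on 4 and 0.237 on X. With 2 kb either side of the start, ratios were 1.42 for zinc finger genes and 2.01 for vomeronasal receptors, both without a call, 13.2 for germline genes with a call, 0.838 for olfactory receptors, 0 for limb genes and 2.70 for outside lineages. With at least 500 bp, they were 2.58 for vomeronasal receptors without a call, 5.06 for germline genes with one, 0.962 for olfactory receptors, 0.778 for limb genes and 1.34 for other limb cell types. The pooled list gave 0.613 for limb genes and 1.11 for outside lineages, and 10 kb flanks gave 1.37 for outside lineages. Peaks of unique sequence gave 2.02 for vomeronasal receptors without a call and 3.38 for germline genes with one (adjusted permutation p = 0.039), and peaks touching both lists 2.59 for vomeronasal receptors without a call.

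Without replicate 1 or 2, ratios ran from 0.804 to 0.867 for limb genes, 1.12 to 1.73 for outside lineages, 0.803 to 1.03 for germline genes and 1.05 to 1.06 for intergenic sequence. Densities ran from 2.06 to 2.11 on chromosome 7, 1.66 to 1.67 on 17, 1.20 to 1.21 on 4 and 0.342 to 0.345 on X, and domains from 465 to 654. The single lists hold 27613 and 37058 peaks in place of 5583; beyond that, the cause was not tested. Depth was unknown, so what it limits cannot be given.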

Other observations

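The tests in this part were chosen after the patterns were seen. The Nlrp and Skint genes, Drg1 and Sfi1 lie outside the named-gene rule.

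H3K9me3 peaks also lay in gene families outside the fixed lists. Among the Nlrp genes, which encode innate immune and oocyte proteins, 7 of 17 had a replicated peak in the body against 1.71 expected, with 3757 bases in Nlrp5 and 3196 in Nlrp2. Among the Skint genes, which act in the selection of skin T cells, 6 of 11 did against 1.55 expected, with 6654 bases in Skint6 and 4007 in Skint5. Of the Ugt genes, 9 of 22 did against 1.17 expected, but these 9 are overlapping Ugt1a genes of 1 locus, at the low-fold domain on chromosome 1 described above. The hypothesis that other families were enriched was tested on 332 families of at least 8 genes sharing a symbol stem. Stems of the zinc finger, protocadherin, olfactory and vomeronasal lists were left out. Members of the other fixed lists stayed in, so some families overlap those lists: Cyp holds Cyp3a11, and Cdkn holds an imprinted gene of the list. With 20000 shifts, 0 passed after Benjamini-Hochberg adjustment and 6 had an unadjusted permutation p under 0.05. Those 6 were Nlrp (0.0097), Cyp (0.021, 13 of 100 genes), Cdkn, Klra and Scgb (0.025 each) and Ugt (0.028), while Skint had 0.063. In many families so few genes were expected (0.092 for Hoxd) that a count of 0 could not fall under 0.05. How many of the 332 would do so by chance is therefore unknown.

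The assembled ends next to the centromeres held many peaks. On chromosomes 1 to 19 and X, 199 of 5355 replicated peaks (3.72%) lay in the first 1 Mb of gap-free sequence, 4.65 times the 42.8 ± 26.7 (SD) of shifted peaks (two-sided permutation p = 0.0018). The ratio was 2.16 in replicate 1 (p = 0.0034, permutation) and 2.11 in replicate 2 (p = 0.0032, permutation). Chromosomes 3 and 9 held 33 such peaks each, chromosome 16 held 28 and chromosome 4 held 25, and 17 of the 20 chromosomes held at least 1. Peaks of unique sequence made up 47.2% of the 199, against 70.0% of all replicated peaks on chromosomes, so reads from repeat copies could be part of the 4.65-fold excess.

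The replicated peak of highest −log10 p, at 105.8, lay where Drg1 and Sfi1 overlap (chromosome 11, 3191004 to 3197201), with a fold of 3.09 and 90.7% unique words. It is among the 21 peaks in the first 1 Mb of assembled sequence of that chromosome. Like the chromosome 1 domains, it paired a modest fold with a high −log10 p, and its control reads were not analysed here. It was also the widest replicated peak, at 6198 bp against a median of 376 bp, so its width stays open as a reason. Of the 10 peaks of highest −log10 p, 3 lay on an unplaced contig, and the next after Drg1 and Sfi1 (chromosome 2, 98666139 to 98667400) had 37.9% unique words. Ranks 3 and 5 lay close together on chromosome 17 (39847455 to 39848885 and 39842995 to 39846769), with 85.2% and 94.1% unique words. Ranks 7 and 9 lay at Drg1 again (84.8% and 90.4%), and rank 8 lay on chromosome 13 (119597588 to 119598233, 80.4%). Drg1 and Sfi1 had 12180 and 10764 bases under replicated peaks.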
